A study of Mus musculus with 12 samples.

How the data were processed

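Whole-genome bisulfite libraries of primary mouse articular chondrocytes were compared, 3 labelled Adeno-Cre and 3 labelled Adeno-GFP. The group and replicate number of each library were taken from its labels. Another 6 RNA-seq samples of the series were not analysed here. Per the submitters' processing notes, Bismark 0.9.0 and the mouse genome build mm9 were used to make the files. Trimming, duplicate removal, the handling of overlapping read pairs and any filter on coverage are not given in the sources used here. The deposited tables list, for each cytosine in CpG context on either strand, the percent of reads that called it methylated and the counts of methylated and unmethylated reads, per the values in the files, which have no header. The percent values were checked against the counts and were the share of methylated reads. Reads of both strands were kept apart by the authors. Only chromosomes 1 to 19, X, Y and the mitochondrial genome were listed. Because the values are read counts, duplicates that were not removed would be counted as independent reads, and strain variants at CpGs would be read as unmethylated.

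From these files the positions of all libraries were merged, and adjacent cytosines on opposite strands were joined into CpG dinucleotides by summing their counts. Cytosines without a call on the partner strand in any library were left out of all levels and of the reads counted at CpGs, which took 3.20% of the reads on chromosome 2, 7.93% on chromosome X and 74.4% on chromosome Y. The chi-square per window between libraries of a group was 1.48 to 1.57, where sampling of independent calls alone gives 1. Duplicate reads give more, as do calls at several CpGs of the same read where they are alike. No pair of libraries stood apart, and each was counted as a replicate, as labelled. The genome was divided into windows of 1000 bp starting at position 1, and windows with at least 3 CpGs and at least 20 reads in every library were tested, 852531 of the 1984525 windows with 3 CpGs on the autosomes and X (43.0%). Reads are counted throughout at each CpG they cover, so a read over several CpGs of a window counts several times. Counted so, the median tested window had 45 to 64 reads depending on the library. With binomial sampling of independent calls alone, the level of a typical window in a single library would vary by 5.08 points (SD). Depth thus limits the comparison of single windows more than that of pooled classes. Single CpGs were to be tested at 10 or more reads in every library, but 19341 CpGs reached this, under the minimum of 100000 set beforehand, and the minimum of 5 reads set for that case was used.

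Levels of the genome, of chromosomes, of CpG density classes and of mean level classes were the methylated share of all reads in the class, and were compared between the groups with exact two-sided permutation tests, with Benjamini-Hochberg adjustment over the classes. For 3 against 3 libraries the smallest p is 0.1, so that none of these can pass 0.05. Windows and CpGs were tested with a logistic model of the methylated and unmethylated counts with a level per group, the dispersion taken from the residual deviance and moderated across windows by squeezeVar of limma 3.58.1, in R 4.3.3, with Benjamini-Hochberg adjustment. The windows named in the text are the 6 with the largest difference in each direction, or all where fewer pass, among those with adjusted p under 0.05 whose groups do not overlap. These choices were made before the data were examined. Tables were handled with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.

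The window and CpG tests were tried on simulated data of the same depths and levels, with 200 changed in each simulation, only after the planned test had been run on the real libraries. The planned test gave too many false calls there. Counting it, 3 forms of the test were tried: as planned, with a lower limit of 1 (the binomial value) on the dispersion, and with that limit and a trend of the dispersion over depth. The spread between simulated libraries was itself adjusted so that the median dispersion of windows met the real one. The same setting was used at every depth and for CpGs, whose dispersion was not matched. The planned test is kept as the main result, and the last form is given beside it as an alternative chosen after the data had been seen.

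Alternatives were edgeR 4.0.16, limma on log2 of methylated over unmethylated reads with 1 added to each, the replicate number as a block, the genome-wide level as an offset, thinning to the shallowest library, other window sizes and read minimums, removal of the deepest windows, Fisher's exact test on pooled reads, and leaving out each library in turn. For edgeR a common dispersion was estimated only on the windows or CpGs with the most reads, and was used for all of them. Promoters, gene bodies, gene lists and named genes had been planned, but need gene positions on mm9. The annotation used here was of GRCm38, and coordinates were not converted between builds, so these were not run.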

Results

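Articular chondrocytes, the cells that make and maintain joint cartilage, were grown as primary cultures from mice whose Dnmt3b gene is floxed, that is, has recombination sites on both sides of a part of it. Dnmt3b encodes a de novo DNA methyltransferase, an enzyme that adds methyl groups to cytosines, mainly in CpG dinucleotides. The cultures had been infected for 72 h, at a multiplicity of 100, with an adenovirus that expresses Cre recombinase (Adeno-Cre), which removes DNA between such sites, or green fluorescent protein (Adeno-GFP), the control. Whole-genome bisulfite sequencing, which reads unmethylated cytosines as thymines, covered 3 Adeno-Cre and 3 Adeno-GFP libraries. RNA-seq of another 6 samples was not analysed here. Reads were counted at each CpG they cover. At nuclear CpGs they numbered 90266498, 99371170 and 74176360 in Adeno-Cre 1, 2 and 3. In Adeno-GFP 1, 2 and 3 they numbered 95565844, 88229682 and 69129911. Over the 18389642 CpG dinucleotides with calls on both strands in the merged libraries, this was a mean of 3.76 to 5.40 reads per CpG. Between 90.5% and 95.7% of these CpGs had a read in a given library. CpGs of the genome without such calls are not in this share. Nothing in the labels says that the 3 libraries of a group came from separate animals or cultures. The p-values thus rest on the spread between these libraries, which may be technical. For 1 kb windows they rest mostly on the spread shared across windows (49.0 prior degrees of freedom) and less on that of the window itself (4).

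The first question was whether the libraries labelled Adeno-Cre had lost DNA where Dnmt3b lies. No stretch of chromosome 2, which carries Dnmt3b, was depleted in the libraries labelled Adeno-Cre beyond what other chromosomes showed. Runs of 5 kb with at least 100 reads in the Adeno-GFP libraries made up 88.5% of all such runs on chromosome 2, and the lowest ratio of Adeno-Cre to Adeno-GFP reads, scaled to the total of each library, was 0.310, at mm9 chromosome 2, 139298001 to 139303000. That run rested on 7, 27 and 7 reads in the Adeno-Cre libraries and on 27, 39 and 49 reads in the Adeno-GFP libraries. Among 20 chromosomes the lowest ratio of chromosome 2 ranked 9, and the lowest ratio of the genome was 0.147, on chromosome 6. With a library left out, the lowest ratio of chromosome 2 was 0.180 to 0.345, for which ranks were not computed. With runs of 3 kb, of which 73.6% could be tested, and of 10 kb chromosome 2 ranked 5, with lowest ratios of 0.268 and 0.375. Turned around, the lowest ratio of Adeno-GFP to Adeno-Cre was 0.397 on chromosome 2 and 0.183 in the genome. The gene itself was not placed on mm9, because the annotation used was of another build, so its depth is not given. A deletion shorter than 3 kb or one whose excised circles persisted would not be seen. Neither would an excision in part of the cells stand out, since the median over chromosomes of the lowest ratio was 0.315. The comparisons that follow are therefore between libraries as labelled.

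The purpose of the design, per the series title, was the part that Dnmt3b plays in cartilage and in chondrocyte metabolism. Across the whole genome the groups differed by less than the spread between libraries. CpGs of Adeno-Cre libraries were methylated at 69.5% ± 0.162 (SD, n = 3) and those of Adeno-GFP libraries at 69.5% ± 0.318 (SD, n = 3), a difference of -0.0111 ± 0.206 percentage points (SE). The exact two-sided permutation test gave p = 1 with n = 3 per group, where the smallest p that 3 against 3 libraries allow is 0.1. Weighting each CpG equally, over CpGs with at least 5 reads in every library, turned the direction. The level was then 0.0901 ± 0.0252 points (SE) higher in Adeno-Cre, with the groups not overlapping and an exact permutation p = 0.1. Leaving out Adeno-GFP 2 turned it as well, to 0.167 points, as did leaving out Adeno-Cre 1 (0.0128) or Adeno-Cre 3 (0.0551).

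Methylation was lower in CpG-dense windows in both groups. Sparse windows of 1 kb with 3 to 9 CpGs were methylated at 76.6% ± 0.0442 (SD, n = 3) in Adeno-Cre and 76.5% ± 0.0621 (SD, n = 3) in Adeno-GFP. Windows of 40 to 59 CpGs were at 19.5% ± 0.158 and 19.99% ± 0.271 (SD, n = 3 each), and those of 60 or more, the density of CpG islands, at 7.25% ± 0.05003 and 7.48% ± 0.200 (SD, n = 3 each). Chance separates the groups in a class 10% of the time, and the 5 classes share the same libraries, so they are not independent. The groups did not overlap in 3 classes. In 2 of them Adeno-Cre was higher, by 0.148 ± 0.0440 points (SE) at 3 to 9 CpGs and by 0.111 ± 0.0369 points at 10 to 19. In the class of 40 to 59 CpGs the level was lower by 0.491 ± 0.181 points (SE) in Adeno-Cre. All 5 exact permutation tests had adjusted p of at least 0.167. When windows rather than reads were averaged, the groups stayed apart at 3 to 9 CpGs (0.140 points) and at 10 to 19 (0.0895 points). The difference at 40 to 59 CpGs shrank to -0.0158 points and the groups overlapped, and that at 60 or more went from -0.225 to -0.00863 points. With a library left out, the difference between reads was 0.114 to 0.174 points at 3 to 9 CpGs and 0.0840 to 0.145 at 10 to 19. At 40 to 59 CpGs it was then -0.635 to -0.366. At 20 to 39 CpGs the difference of -0.199 points between reads became 0.0499 between windows. With a library left out it ranged from -0.288 to -0.118 (without Adeno-Cre 3), and that at 60 or more CpGs from -0.338 (without Adeno-GFP 1) to -0.152.

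**Figure D1:**
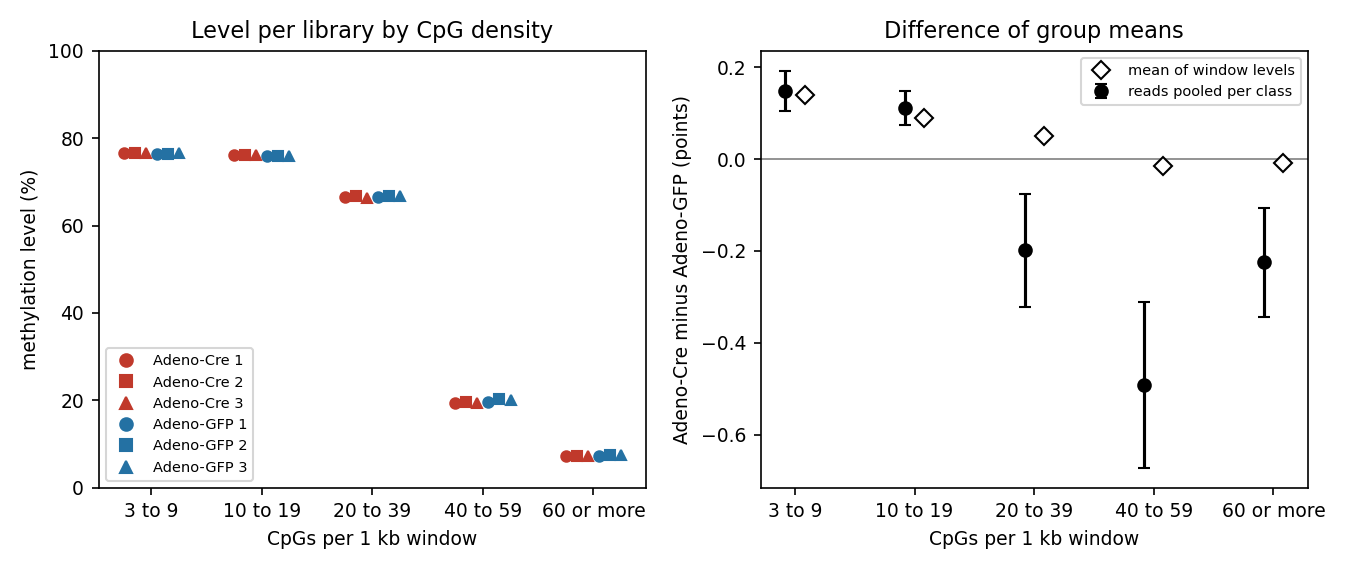
Methylation level in percent of each library in 1 kb windows grouped by number of CpGs (left), and Adeno-Cre minus Adeno-GFP in percentage points (right; filled points are reads pooled per class with SE, open points the mean of window levels). Levels fell from 76.6% to 7.25% with density in Adeno-Cre, and the pooled difference of -0.491 points at 40 to 59 CpGs shrank to -0.0158 points when windows were averaged.

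Sorted by their mean level over all 6 libraries, 26037 windows were below 10%, 76558 between 10% and 50%, 322493 between 50% and 80%, and 427443 above 80%. Windows below 10% were at 2.73% ± 0.0183 (SD, n = 3) in Adeno-Cre and 2.73% ± 0.0734 (SD, n = 3) in Adeno-GFP. Partially methylated windows between 50% and 80% were 0.138 ± 0.0486 points (SE) higher in Adeno-Cre without overlap, with an adjusted exact permutation p of 0.4 over 4 classes, and groups overlapped in the other classes. Over 22 chromosomes, mitochondrial DNA included, groups were apart on 1, chromosome 2, at 72.9% ± 0.0684 in Adeno-Cre and 72.6% ± 0.191 in Adeno-GFP (SD, n = 3 each). There 3 windows held 27.3% of the reads, and without the deepest windows, an alternative chosen after the data had been seen, the difference turned from 0.305 to -0.0475 points and the groups overlapped. Chance separates 3 from 3 libraries 10% of the time, and the smallest adjusted p over chromosomes was 0.99 by the exact permutation test.

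Chromosome X carried dense CpG windows of intermediate methylation in both groups. Windows with 60 or more CpGs had a median level of 32.2% on chromosome X (196 windows) and 1.37% on the autosomes (8692 windows). Between 20% and 60% methylation lay 84.7% of these windows on chromosome X and 2.15% on the autosomes. Over all 6 libraries 4914 reads were listed on chromosome Y and 17098845 on chromosome X. In females the CpG islands of the inactive X chromosome are methylated. The level of the dense X windows was 32.02% ± 0.160 (SD, n = 3) in Adeno-Cre and 31.99% ± 1.04 (SD, n = 3) in Adeno-GFP, with an exact permutation p = 1. At 40 to 59 CpGs the X windows were at 41.4% ± 0.164 in Adeno-Cre and 42.5% ± 0.449 in Adeno-GFP (SD, n = 3 each), a difference of -1.05 ± 0.276 points (SE) without overlap. Its exact permutation p was 0.1, adjusted 0.5, and as a mean of windows it was -0.613 points with overlap.

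**Figure D2:**
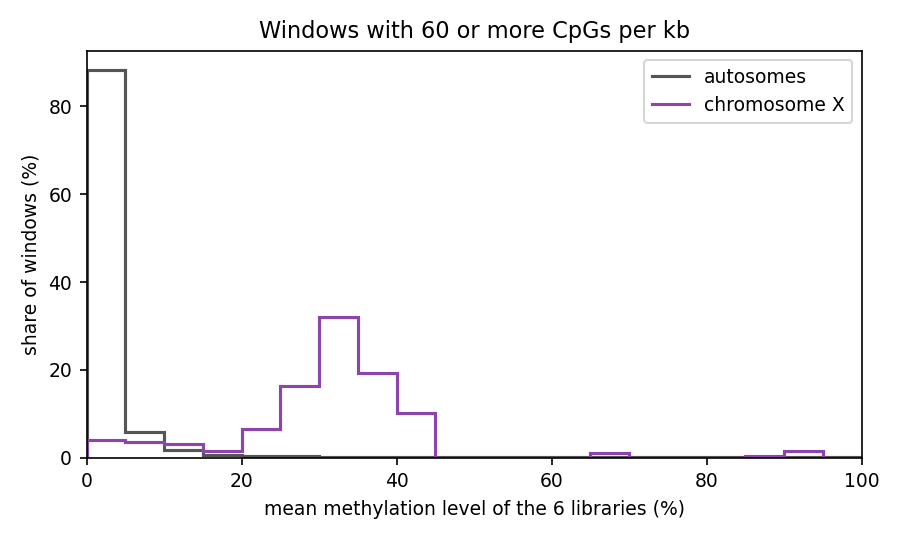
Share of 1 kb windows with 60 or more CpGs, in percent, by mean methylation level of the 6 libraries in steps of 5 points, on autosomes and on chromosome X. Autosomal windows pile up below 5% (88.2% of them), and those of chromosome X lie mostly between 20% and 45%, with a median of 32.2%.

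At single windows, 13 of 852531 tested passed the threshold, 10 with higher and 3 with lower methylation in Adeno-Cre (moderated quasi-binomial test with limma's squeezeVar, Benjamini-Hochberg adjusted p under 0.05). The same test gave 17.3 false calls per simulation on simulated libraries. Those had the same setting of spread between libraries at every depth, which real deep windows need not have. Of the 13 windows, 7 had at least 160 reads in every library, so the 13 cannot be weighed directly against the 17.3. Another split of the 6 libraries gave 37. Fits on other sets called other windows in part. Without Adeno-Cre 1 there were 3 higher and 6 lower, of which 2 were among the 13. Leaving out any other library gave more higher than lower calls. Of these, from 5 (without Adeno-GFP 1 or Adeno-GFP 2) to 10 (without Adeno-Cre 2) were among the 13. Windows of 5 kb gave 0 higher and 4 lower. Differences of at least 10 points were seen in 9 of the 13. Groups did not overlap in 12 of the 13, and in 9.85% of all windows tested, where chance gives 10%. The widest were at mm9 chromosome X, 131136001 to 131137000, and at chromosome 8, 112482001 to 112483000. The X window had 49.5% ± 2.78 in Adeno-Cre and 17.8% ± 8.93 in Adeno-GFP (SD, n = 3 each, adjusted p = 0.0124), on 38 to 140 reads per library over 34 CpGs. The window of chromosome 8 had 77.1% ± 7.63 and 45.8% ± 9.88 (SD, n = 3 each, adjusted p = 0.0184), on 49 to 111 reads over 17 CpGs. With a library left out, the X window stayed called in 3 of 6 fits, with differences of 26.6 to 34.6 points over all 6, and that of chromosome 8 in 2, with 26.9 to 37.0 points. On chromosome 9, 15043001 to 15044000, the level was 40.1% ± 4.99 in Adeno-Cre and 17.8% ± 2.34 in Adeno-GFP (SD, n = 3 each, adjusted p = 2.33e-06), on 254 to 389 reads over 43 CpGs. Its neighbouring windows differed by -2.16 and 4.99 points. Of the 9 windows named by the rule it alone stayed called in all 6 fits that left out a library, but not with edgeR (adjusted p = 0.0803) or limma (adjusted p = 0.984). The rule also named windows with higher levels in Adeno-Cre on chromosome 7, 127648001 to 127649000 (25.1 ± 3.81 points, SE, adjusted p = 0.0300), chromosome 11, 5906001 to 5907000 (21.9 ± 6.67 points, adjusted p = 0.0184) and chromosome 12, 24485001 to 24486000 (10.8 ± 1.82 points, adjusted p = 0.0300). The windows before and after differed by 14.6 and -1.98 points on chromosome 7, 35.6 and 0.134 on chromosome 11, and -9.99 and -3.79 on chromosome 12. For such neighbours a read in every library was enough, with no minimum of CpGs, and their depth is not given here. None of these neighbours was among the 13 called windows, so a wider change cannot be read from them. Lower levels in Adeno-Cre were found on chromosome 7, 25413001 to 25414000 (-28.5 ± 4.48 points, SE, adjusted p = 0.0158), chromosome 5, 130096001 to 130097000 (-27.0 ± 6.12 points, adjusted p = 0.0339) and chromosome 17, 34256001 to 34257000 (-7.83 ± 2.73 points, adjusted p = 0.00395). With a library left out, the first of these on chromosome 7 was called in 0 of 6 fits, that of chromosome 5 in 1, those of chromosomes 11 and 12 and the lower one of chromosome 7 in 2, and that of chromosome 17 in 3. Whether any of these windows lies in a gene is not given here, because the annotation used was of another build.

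**Figure D3:**
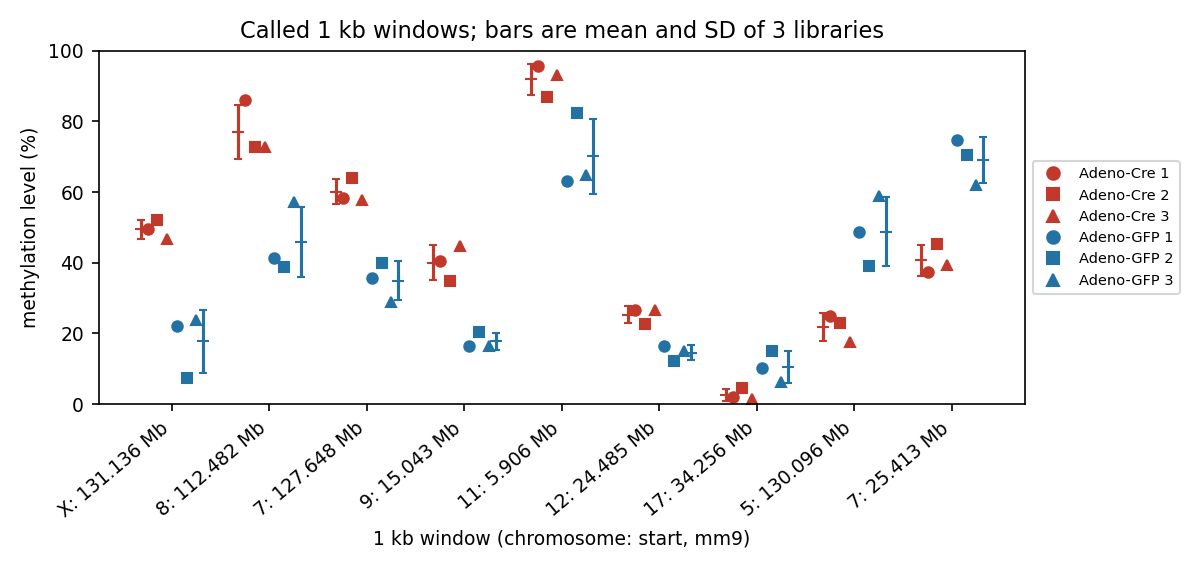
Methylation level in percent of the 6 libraries in the 9 windows of 1 kb named by the rule, with the mean and SD of each group beside the points. In each window the 3 Adeno-Cre libraries lie apart from the 3 Adeno-GFP libraries, which the rule requires. Differences run from 31.7 points on chromosome X to -28.5 points on chromosome 7.

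The count of windows depended on the test. edgeR's quasi-likelihood test called 1 window, at chromosome 8, 83263001 to 83264000, which the rule does not name and which was singled out after its values were seen. It had 6.26% ± 0.679 in Adeno-Cre and 1.05% ± 0.120 in Adeno-GFP (SD, n = 3 each; edgeR adjusted p = 0.0161), on 285 to 772 reads over 109 CpGs. limma on logit levels called 0, with 41583 windows at an unadjusted p under 0.05 against 41033 in the main test, which is 4.81% of those tested. Of the 13 windows, 9 stayed called after the dispersion was given a trend over depth and a lower limit of 1, a form of the test chosen after the calls had been seen. Lost among the named ones were the higher window of chromosome 7 (adjusted p = 0.0654) and those of chromosome 12 (0.143) and chromosome 5 (0.0654). In simulations on the real depths the planned test recovered 18.7% of windows changed by 20 points, 46.0% at 30 points and 76.7% at 40 points, with 17.3 false calls per simulation, and the later form recovered 23.3%, 64.7% and 88.7% with 2 false calls. Averaged over 100 kb, 95% of 25505 windows differed by between -2.61 and 2.62 points, and 0 were called by the main test, with 1200 at an unadjusted p under 0.05. That window size was chosen after the data had been seen.

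**Figure D4:**
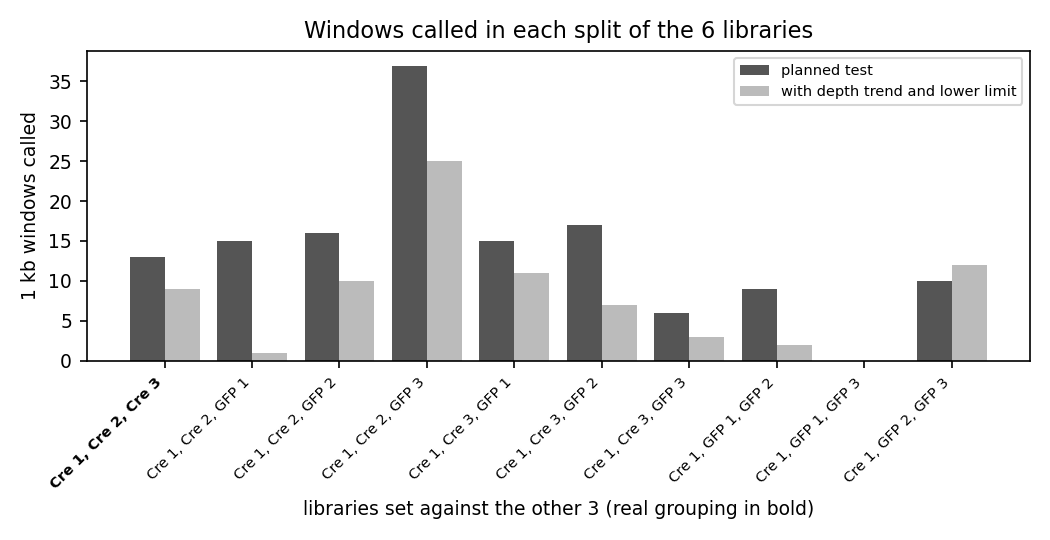
Number of 1 kb windows called for the real grouping (first pair of bars, bold) and for the other splits of the 6 libraries into 3 and 3, by the planned test and by the form with a depth trend and a lower limit. The real grouping has 13 and 9 windows, and the highest other split has 37 and 25.

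For single CpGs the calls were outnumbered by the false calls of the same test on simulated data. The planned test called 3478 of 1324027 CpGs with at least 5 reads in every library, 1650 higher and 1828 lower in Adeno-Cre. Without any 1 Adeno-Cre library the calls were mostly lower, from 6942 to 7494 against 2583 to 2681 higher, and without any 1 Adeno-GFP library mostly higher, from 6079 to 6700 against 2429 to 2544 lower. Applied to simulated CpGs of the same depths with 200 changed, it made 3568 false calls per simulation and recovered 15% of changes of 80 points. The spread of simulated CpGs was set from windows. By the planned test 5.73% of unchanged simulated CpGs had an unadjusted p under 0.05, against 6.43% of the real ones, so the match is loose. In 10.1% of the real CpGs the residual deviance within groups was under 1e-09, which sets the estimated dispersion to 0. With the lower limit and the depth trend, 0 CpGs were called by the limma-moderated test, 15872 had an unadjusted p under 0.05, and 0% of simulated changes of 80 points were recovered. edgeR called 0 with 30417 at an unadjusted p under 0.05, and Fisher's exact test on reads pooled per group called 1. edgeR, limma and Fisher's exact test were not tried on simulated CpGs.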

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

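Chosen after the data had been seen were the form of the test with a depth trend and a lower limit, windows of 100 kb, the mean of window levels over the genome, the alternatives for chromosome 2, and CpGs with at least 10 reads. Of 57 recomputed levels, 50 kept their direction and 7 turned. The genome-wide difference of -0.0111 points became 0.0901 over CpGs with at least 5 reads and 0.0991 as the mean of window levels, and ranged from -0.141 to 0.167 with a library left out, positive without Adeno-Cre 1 (0.0128), Adeno-Cre 3 (0.0551) or Adeno-GFP 2 (0.167). The difference at 20 to 39 CpGs per kb became 0.0499 as the mean of window levels. The cause was not tested for any of these. The difference on chromosome 2 of 0.305 became -0.0475 without the deepest windows, which took 29.7% of its reads, and was 0.246 to 0.416 with a library left out. The 13 windows became 1 with edgeR, 0 with limma, 1 at 500 bp, 4 at 5 kb, 0 at 100 kb, 6 with at least 40 reads and 8 without the deepest windows, and ranged from 8 (without Adeno-GFP 2) to 23 (without Adeno-Cre 2) with a library left out. The cause was not tested. The later form of the test called 9, all among the 13. For the 9 named windows, 68 of 132 recomputed tests stayed past the threshold. The window of chromosome 9, 15043001, stayed called in all 6 fits with a library left out and in 7 of 9 other settings, with adjusted p from 9.15e-07 to 0.984. The 3478 CpGs became 0 with edgeR, with the genome-wide level as an offset, with the limit and trend, and at 10 or 15 reads, became 1 with limma or Fisher's exact test, and rose to between 8508 and 10104 with any library left out. The cause was not tested. The fits with the offset and with a block were solved by iteration, and the main test was not. The 0 with the offset can thus not be laid to the offset alone. The replicate number as a block gave 0 CpGs. In that quasi-binomial fit 247101 CpGs (18.7%) had an unadjusted p under 0.05, against 6.43% in the main test. Why was not tested, so those 0 calls cannot show that no CpG differed. For windows the block gave 12, 10 of them among the 13. Lost were those named on chromosome 8 (adjusted p = 0.0546), chromosome 5 (0.0724) and, with higher levels, chromosome 7 (0.0582). The block cannot move the genome-wide difference of -0.0111, but its SE went from 0.206 to 0.113 points. In windows, same-numbered libraries deviated from their group means with correlations of -0.00158 to -0.000493. Sampling weighs heavily on single windows, so whether the numbers pair the libraries cannot be told from this. The lowest ratio of reads on chromosome 2 was 0.305 when scaled to that chromosome, and 0.180 (without Adeno-Cre 2) to 0.345 with a library left out. Alternatives for promoters, gene bodies and gene lists were not run. At this depth the planned test recovered 2% of simulated window changes of 10 points and 76.7% of those of 40.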

Other observations

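Chosen after the result was seen were both tests on mitochondrial DNA, both counts over regroupings, the narrower test for strain variants, the reckoning of what the wider one could reach, and the class of intermediate windows. Some CpG-dense autosomal windows were of intermediate methylation. Of 100981 autosomal windows with 20 or more CpGs, 4685 (4.64%) lay between 35% and 65% in each of the 6 libraries. Imprinted control regions, methylated on the copy from a single parent, are known to have such levels. Whether any of the 4685 windows lies in such a region was not tested, because genes were not placed. The windows were at 50.7% ± 0.257 (SD, n = 3) in Adeno-Cre and 50.7% ± 0.00994 (SD, n = 3) in Adeno-GFP, means that the range required of every library holds close together. The 8181 autosomal windows with 60 or more CpGs and a mean level under 10% were at 1.86% ± 0.0101 in Adeno-Cre and 1.85% ± 0.0336 in Adeno-GFP (SD, n = 3 each), which bounds from above the share of cytosines that escaped conversion there.

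A few windows held very many reads. The deepest, chromosome 2, 98507001 to 98508000, held 9737550 reads over 19 CpGs, 29067 times the median window, and was among the 13 called windows, at 85.3% ± 0.0464 in Adeno-Cre and 85.2% ± 0.0280 in Adeno-GFP (SD, n = 3 each). On chromosome 17, the deep window 39982001 to 39983000 ranged from 28.6% in Adeno-Cre 3 to 38.9% in Adeno-Cre 1.

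Regrouping the 6 libraries gave 10 splits into 3 and 3, which cannot give a share under 0.1. As many windows as the real grouping, which had 13, were called by 6 of the 10 splits, the real one included, and the highest other had 37. That split set Adeno-Cre 1, Adeno-Cre 2 and Adeno-GFP 3 against the rest, and the cause of its higher count was not tested. For single CpGs the real grouping had 3478 and the highest other 3856, with 6 of the 10 as large.

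Mitochondrial CpGs were called methylated at 69.3%, 64.7% and 57.5% in the Adeno-Cre and at 69.5%, 70.1% and 68.1% in the Adeno-GFP libraries, although this DNA is usually taken as nearly unmethylated, so it could not serve as a measure of conversion. Nuclear copies are argued against by depth, since mitochondrial CpGs were read at least 200.45 times as deeply as nuclear ones. A candidate explanation is reads that escaped conversion, which need not be alike on both strands. Strands differed by a median of 33.2 points over the 224 of 298 CpGs with at least 20 reads per strand in every library, against 6.57 points at 1085 autosomal CpGs of 30% to 80% with at least 50 reads per strand over all libraries, so the minimums were unlike. Strand-biased methylation in the cells stays open and was not tested.

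Single unmethylated CpGs, at 3% or less amid neighbours at 80% or more, made up 12.1 per 1000 in 27 of 1294 bins of 2 Mb, chosen for having at least 5 per 1000, and 0.169 per 1000 in the others, with the longest segment at chromosome 2, 150000001 to 166000000 (485 such CpGs). A hypothesis is that segments from another mouse strain carry variants that read as unmethylated. Cytosines without a call on the partner strand, which some variants would leave, were 0.948 times as frequent in these bins as elsewhere, under the bound set beforehand, but that bound was out of reach: as many of them as there are single CpGs would give 1.39. Over those at 3% or less, which were 11.8% of such cytosines in these bins and 4.01% elsewhere, the ratio was 2.80, below the 3 taken as deciding, so strain variants stay open. Reads shared between repeated copies stay open too, with the depth of the single CpGs at 1.103 times that of their neighbours (quartiles 0.889 and 1.36).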
